A study of Mus musculus with 10 samples.

How the data were processed

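Total RNA from the livers of 1-year-old mice was labelled with Cy3 and hybridised to Agilent mouse expression arrays, 1 sample per array. The labels put 5 arrays in the wild-type group and 5 in the group lacking the nuclear orphan receptor TAK1/TR4, whose gene is Nr2c2, and give C57BL/6 as the strain of both. The labels do not state that each array holds RNA of a separate mouse, so p-values measure the spread between these samples. Arrays are named here by group and replicate number, WT1 to WT5 and KO1 to KO5. WT1 to WT4 lay on slide 1, WT5 and KO1 to KO3 on slide 2, KO5 on slide 3 and KO4 on slide 4. Slide 4 was scanned on a later day than the other 3 slides.

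The authors quantified each image with Agilent Feature Extraction 9.5.1.1, per the file headers, and version 9.5 is named in the submitters' processing notes. The deposited intensity values were background-subtracted and detrended within each array by that program, per the file headers, and were not normalised between arrays. The deposited series table held the same intensity values as the scanner output, with a largest difference of 0 on every array, on a linear scale with no centring. Its column medians ran from 80.0 to 107.6. Feature Extraction's flags for signal above background, outlier spots and saturation came with the deposited scanner files. Probe coordinates are those of the files, whose headers give the mouse build mm7, and no genome was used here to place probes in exons, introns or untranslated regions.

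Processed intensities were put on the log2 scale with no pseudocount, and each array's 75th percentile over the non-control probes was subtracted. Spots flagged as outliers were set to missing, and replicate spots of a probe were averaged. Of 41174 non-control probes, 23266 were well above background on at least 4 of 5 arrays of at least 1 group and were kept. Gene symbols were updated through a RefSeq gene table of a later mouse assembly, used for names only. This matched 23075 probes by RefSeq accession, 6582 by current symbol and 3077 by an older symbol, and 8440 probes kept the name in the files. Each gene was represented by its probe with the highest mean signal over all arrays, which left 15808 genes. Of 396 further kept probes of the genes called below, 380 had the same sign as the chosen probe, 290 of them with an unadjusted p under 0.05, and 0 had the opposite sign at that level.

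Knockout and wild type were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene with an adjusted p under 0.05 is said here to have changed. All tests were two-sided. Log2 differences are knockout minus wild type and are given with the standard error of the fit. Exact permutation tests of 5 against 5 arrays cannot give a p under 0.0079. For a gene not well above background on any array of 1 group, the fold is a bound. It sets the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background on that array. Named genes above background on 1 or 2 arrays of a group are given the same bound, with the values of those arrays kept.

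The number of arrays limits the precision, and between 51.0% and 62.4% of probes were well above background on each array. On simulated arrays with the means and spreads of these 15808 genes and 200 changed genes, the fit of knockout against wild type recovered 40.0% of genes changed by 0.5 on the log2 scale, 74.0% of those changed by 1, 90.0% of those changed by 2 and 100.0% of those changed by 3. Of its 159 calls, 7 were of genes that had not been changed, and it made 0 calls on simulated arrays with no changed gene. The simulated genes varied independently of each other and with the same spread in both groups. Real genes are correlated and the knockout arrays varied more, so these rates need not hold for the real arrays.

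Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 34 of 35 lists with at least 5 tested members. The 67 missing values were replaced by the gene's mean for the list tests. Lists, alternatives and the rule for the genes named were fixed before the data were examined. The rule took Nr2c2, the 8 genes with the largest fold in each direction, up to 4 genes per direction with 1 group not above background, up to 3 members of each list with the smallest p among those changed or otherwise the 1 with the smallest p, 14 readouts fixed in advance (Cd36, Cidea, Cidec, Mogat1, Pparg, Srebf1, Fasn, Scd1, Apoe, Tnf, Ccl2, Adgre1, Cyp7a1 and Pck1), and changed genes within 20 Mb of Nr2c2. The genes with the largest fold had to have a gene symbol, all knockout arrays on one side of all wild-type arrays and signal above background on at least 4 arrays of each group.

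The alternatives were normexp background correction with quantile normalisation, quantile normalisation alone, scaling to the median of probes above background on all arrays, the deposited values without scaling, no filter or a stricter filter on dim probes, outlier spots kept, the mean of a gene's probes, a mean-variance trend, array weights, slide as a fixed or random block, slide 2 alone, the replicate number as a block, a Welch test per gene in place of limma (an alternative only), 2 other thresholds, 2 other list tests and leaving out each array. Leaving out KO2 and KO4 together was added after the data were seen. With slide as a fixed block only slide 2 holds both groups, so the blocked log2 differences are those of KO1 to KO3 against WT5 alone. The p-values of that fit and of slide 2 assume that WT5 varies like the other arrays. WT5 and KO1 to KO3 also took part in the main fit that called the genes. Values within slide 2 given beside called genes are therefore not an independent check on slide. For the genes with the largest fold the rule above, which asked for separated groups, fixed the sign of those values.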

Results

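Liver RNA of 5 wild-type samples and 5 samples from mice lacking the nuclear receptor TAK1/TR4 was profiled at 1 year of age, to ask how loss of the receptor alters liver gene expression in a study of hepatic steatosis, inflammation and insulin resistance. The 75th percentile of probe signal lay between 950.3 and 1344 on the 10 arrays. Correlations between arrays, across genes, were 0.988 to 0.994 within wild type and 0.965 to 0.988 within knockout. The first principal component held 33.6% of the variance and placed all 5 wild-type arrays below all knockout arrays. KO2 had the highest score on both leading components and KO4 the lowest on the second.

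**Figure D1:**
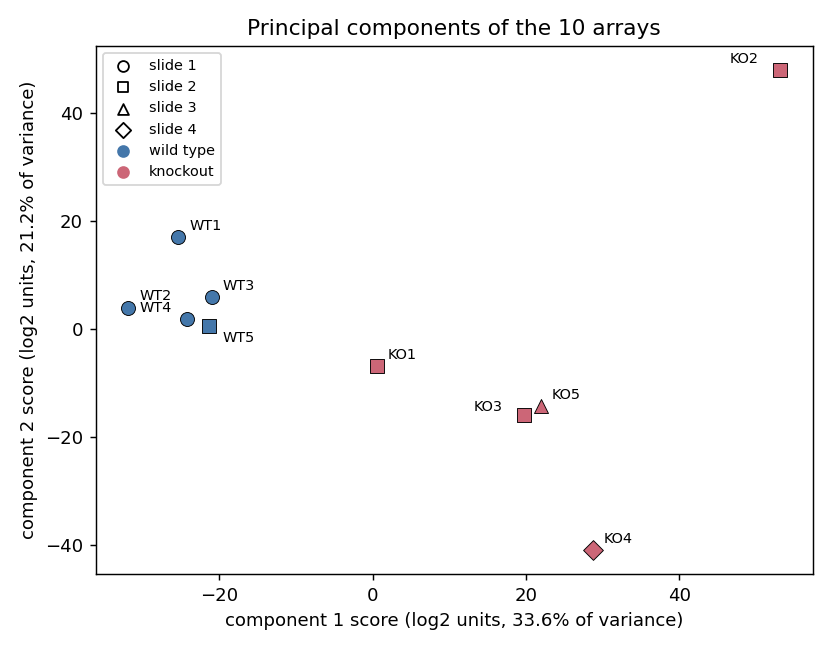
Scores of the 10 arrays on the first and second principal components of log2 signal, in log2 units, with colour for genotype and marker shape for slide. The wild-type arrays lie between -31.9 and -21.0 on the first component and the knockout arrays between 0.49 and 53.1, and WT5, on slide 2 with 3 knockout arrays, lies among the wild-type arrays.

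The files place 3 probes at the locus of the deleted gene on chromosome 6 (mm7). Both probes named Nr2c2 in the files were well above background on all 10 arrays and neither was lower in the knockout. The probe at 92187254 to 92187312 differed by 0.36 ± 0.13 (adjusted p = 0.139, exact permutation p = 0.032, n = 5 per group), and by 0.38 within slide 2. The probe at 92245007 to 92245066 differed by 0.44 ± 0.11 (adjusted p = 0.043 over probes, exact permutation p = 0.016). Another probe lies between them at 92237812 to 92237871, with the sequence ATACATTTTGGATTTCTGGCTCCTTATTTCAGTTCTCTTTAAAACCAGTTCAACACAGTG. The files give it the name of a cDNA, describe the product as the Nr2c2 protein, and list its coordinates in the opposite direction to those of the other 2. It was above background on all 5 wild-type arrays and on 0 knockout arrays, so that it was at least 5.41-fold lower in the knockout (adjusted p = 0.00021, exact permutation p = 0.0079, the smallest possible). Its mean relative to the 75th percentile was -2.22 ± 0.35 (SD, n = 5) in wild type. Within slide 2 it was above background on WT5 and on 0 of 3 knockout arrays, at least 4.30-fold lower. The part of the gene that was deleted is not given in the sources used here. Whether the 2 probes named Nr2c2 lie in that part was not determined. Of the 3 probes only the cDNA probe was lower in the knockout.

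Cidea, Cidec, Mogat1 and Plin4, which act in fat storage, were among the 8 named genes with the largest decreases in the knockout. Cidea, a lipid droplet protein, fell 440.2-fold (log2 difference -8.78 ± 0.74, adjusted p = 0.00055), from 6.76 ± 0.72 (SD, n = 5) in wild type to -2.02 ± 1.72 (SD, n = 5) in knockout. Its relative Cidec fell 28.7-fold (-4.85 ± 0.54, adjusted p = 0.0017). Cfd, the complement factor also known as adipsin, fell 52.8-fold (-5.72 ± 0.77, adjusted p = 0.0037). Mogat1, a monoacylglycerol acyltransferase, fell 12.5-fold (-3.64 ± 0.28, with 4 wild-type values), and the droplet coat protein gene Plin4 fell 9.91-fold (-3.31 ± 0.47). Hamp2, a hepcidin gene, fell 17.3-fold (-4.12 ± 0.64), the orphan receptor gene Gprc5b 13.0-fold (-3.70 ± 0.42) and the N-acetyltransferase family gene Nat8f5 10.9-fold (-3.44 ± 0.64). Within slide 2 the differences were -8.29 for Cidea, -4.93 for Cidec, -7.17 for Cfd, -3.19 for Plin4, -4.30 for Hamp2, -3.96 for Gprc5b and -3.40 for Nat8f5, while the chosen Mogat1 probe had no value on WT5. The rule that chose these genes fixed the sign of their values within slide 2. The call of Nat8f5 was lost without WT2 (adjusted p = 0.053), and those of the other 7 genes were kept without each array in turn.

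Asns, which encodes asparagine synthetase, showed the largest increase, 37.6-fold (5.23 ± 0.53, adjusted p = 0.0012), from -0.71 ± 1.16 (SD, n = 5) to 4.52 ± 0.61 (SD, n = 5). The imprinted long noncoding RNA Meg3 rose 13.8-fold (3.79 ± 0.48, adjusted p = 0.0027) and Rassf4, a Ras-association domain gene, 10.1-fold (3.33 ± 0.40, adjusted p = 0.0022). Acsm2, a medium-chain acyl-CoA synthetase gene, rose 5.63-fold (2.49 ± 0.59), Enho, the adropin gene, 4.98-fold (2.32 ± 0.28), and Socs2, an inhibitor of growth hormone signalling, 4.61-fold (2.21 ± 0.50). The vasopressin receptor gene Avpr1a rose 3.90-fold (1.96 ± 0.24) and the lectin gene Cd209b 3.61-fold (1.85 ± 0.21). Within slide 2 these differences were 5.02 for Asns, 3.87 for Meg3, 3.10 for Rassf4, 2.64 for Acsm2, 2.28 for Enho, 1.81 for Socs2, 2.26 for Avpr1a and 2.48 for Cd209b. Here too the sign within slide 2 was fixed by the rule that chose the genes. The call of Acsm2 was lost without any 1 of 7 arrays (highest adjusted p = 0.100) and that of Socs2 without any 1 of 8 (highest adjusted p = 0.081). The other 6 calls were kept without each array.

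**Figure D2:**
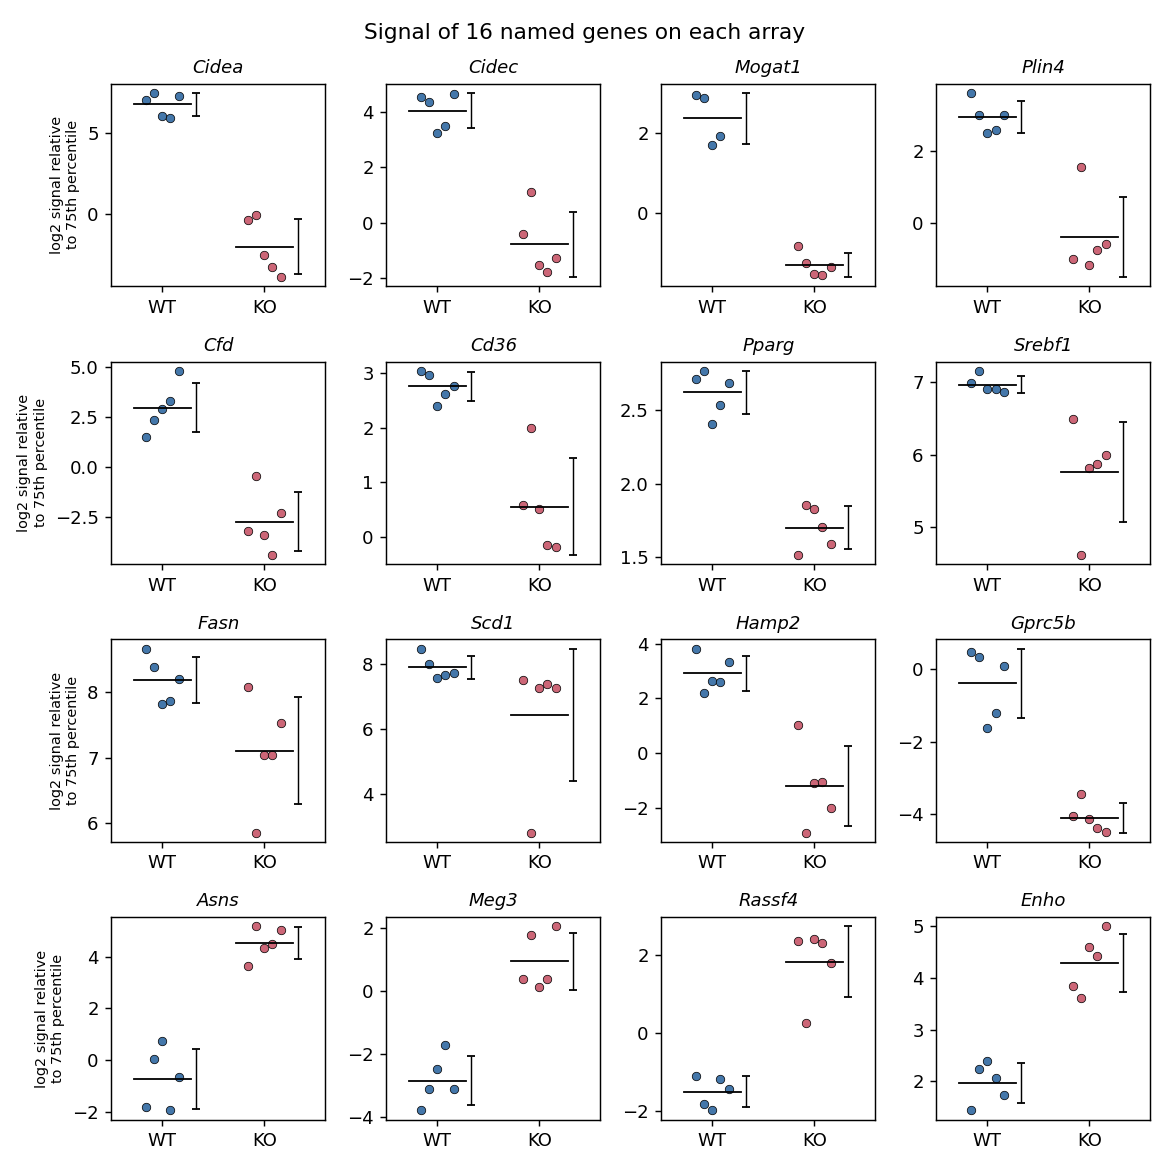
Log2 signal relative to each array's 75th percentile for 16 named genes, with 1 point per array, a line at the group mean and a bar of 1 SD either side. Cidea has means of 6.76 in wild type and -2.02 in knockout, Asns has means of -0.71 and 4.52, and the low Scd1 point of 2.83 is KO2.

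Some genes were measured in 1 group only. Cox8b, a cytochrome c oxidase subunit gene, Dnaaf4, Mpped2 and Serpinb1b were not well above background on any knockout array and were at least 2.91-fold, 2.88-fold, 2.77-fold and 2.71-fold lower there, Serpinb1b having been above background on 4 wild-type arrays. Mirg, an RNA of the same imprinted region as Meg3, Vmn1r53, Olfr1328 and Ephb6 were not well above background on any wild-type array and were above it on 4 knockout arrays, at least 2.67-fold, 1.86-fold, 1.79-fold and 1.78-fold higher. Adjusted p-values of these 8 genes ran from 0.00065 for Dnaaf4 to 0.027 for Ephb6. The calls of Ephb6 and Olfr1328 were each lost without any 1 of 5 arrays (highest adjusted p = 0.067 and 0.069).

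In all, 387 genes were higher and 551 lower in the knockout, 938 of 15808 tested, and 85 of the increases and 134 of the decreases were at least 2-fold. On 845 of the 938 all knockout arrays lay on one side of all wild-type arrays. Among all tested genes this held for 9.62%, against 0.794% by chance. Without scaling between arrays the median of all genes shifted to 0.12 and the changed genes were 314 higher and 157 lower, so the balance of increases and decreases depended on the scaling. The count also depended on the arrays. It was 446, 297, 502, 443 and 463 without WT1, WT2, WT3, WT4 and WT5, and 544 and 505 without KO4 and KO5. With slide as a fixed block 35 genes passed, 16 of them among the 938, and within slide 2 alone 2 passed, none of the 938 (1555 and 699 genes at an unadjusted p under 0.05). The median standard error over all genes was 0.12 on the log2 scale without the block, 0.22 with it and 0.27 within slide 2, where WT5 is the only wild-type array.

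Genes of lipid droplets and triglyceride storage fell as a list. Of 31 measured members 11 fell and 0 rose (19 lower adjusted over the list alone), with a median of -0.53. The list was lower in 5 of 5 knockout arrays, each below all wild-type arrays (camera adjusted p = 3.8e-13, but adjusted p = 0.201 with an estimated correlation). Cidea, Mogat1 and Cidec had the smallest p. Its median was also -0.53 within slide 2. Among 17 genes of fatty acid uptake and PPARG targets 5 fell and 0 rose (6 lower and 1 higher adjusted over the list alone; median -0.20, -0.34 within slide 2, adjusted p = 0.0028, and adjusted p = 0.401 with an estimated correlation). For this list 3 of 5 knockout arrays lay below all wild-type arrays. Pparg, the adipogenic nuclear receptor, fell 1.90-fold (-0.93 ± 0.10), the fatty acid transporter gene Cd36 4.60-fold (-2.20 ± 0.37) and the adiponectin receptor gene Adipor2 1.52-fold (-0.60 ± 0.12). These were -0.96, -1.72 and -0.78 within slide 2, and the call of Adipor2 was lost without WT2 or WT5 (highest adjusted p = 0.065).

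Of 23 genes of de novo lipogenesis 22 had negative differences and 3 fell (7 adjusted over the list alone; median -0.70, -0.71 within slide 2, adjusted p = 4.0e-07, and adjusted p = 0.612 with an estimated correlation). For this list 4 of 5 knockout arrays lay below all wild-type arrays, and KO1, at -0.02 from the wild-type mean, lay among them. Srebf1, the lipogenic transcription factor, fell 2.32-fold (-1.21 ± 0.28), the fatty acid elongase gene Elovl5 2.07-fold (-1.05 ± 0.24) and the transketolase gene Tkt 1.39-fold (-0.48 ± 0.12). Within slide 2 these were -1.23, -1.05 and -0.51. Each of the 3 calls was lost without any 1 of at least 7 arrays (highest adjusted p = 0.096, 0.094 and 0.119). Fasn, fatty acid synthase, differed by -1.08 ± 0.36 (adjusted p = 0.109) and Scd1, stearoyl-CoA desaturase, by -1.45 ± 0.82 (adjusted p = 0.317), and neither passed the test. On KO2 the Scd1 signal was 2.83, against 7.26 to 7.50 on the other knockout arrays.

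Fatty acid oxidation genes and PPARA targets also fell, 15 of 36 measured (19 adjusted over the list alone) with 0 higher. The median was -0.43 and -0.51 within slide 2, and all 5 knockout arrays lay below all wild-type arrays (adjusted p = 4.6e-12, and adjusted p = 0.201 with an estimated correlation). The peroxisomal membrane gene Pex11a fell 1.98-fold (-0.98 ± 0.10), the carnitine acetyltransferase gene Crat 2.06-fold (-1.04 ± 0.16) and the carnitine-acylcarnitine carrier gene Slc25a20 1.37-fold (-0.46 ± 0.07), with -0.98, -1.01 and -0.45 within slide 2. Respiratory chain genes had negative differences for 38 of 42 members, of which 2 fell (2 adjusted over the list alone; median -0.13, -0.17 within slide 2, adjusted p = 2.8e-05, and adjusted p = 0.691 with an estimated correlation). These were the complex I subunit genes Ndufb7 (-0.41 ± 0.07) and Ndufb3 (-0.26 ± 0.06), at -0.49 and -0.36 within slide 2, and the call of Ndufb3 was lost without any 1 of 8 arrays (highest adjusted p = 0.093).

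All 50 ribosomal protein genes had positive differences, and 13 rose (28 adjusted over the list alone; median 0.21, 0.18 within slide 2, adjusted p = 1.9e-15, and adjusted p = 0.414 with an estimated correlation). Rpl12 rose 1.33-fold (0.41 ± 0.08), Rpl10a 1.31-fold (0.39 ± 0.07) and Rps21 1.29-fold (0.37 ± 0.07), with 0.26, 0.44 and 0.30 within slide 2. Rpl12 lost its call without WT2 (adjusted p = 0.052) and Rps21 without any 1 of 4 arrays (highest adjusted p = 0.066). Of 25 cholesterol synthesis genes 3 rose (5 higher and 1 lower adjusted over the list alone; median 0.23, 0.09 within slide 2, adjusted p = 0.018, and adjusted p = 0.747 with an estimated correlation). Sqle, squalene epoxidase, rose 2.99-fold (1.58 ± 0.34), Idi1 1.77-fold (0.82 ± 0.19) and Cyp51 1.71-fold (0.78 ± 0.15), against 0.82, 0.53 and 0.50 within slide 2. Sqle lost its call without any 1 of 4 arrays and Idi1 without any 1 of 6 (highest adjusted p = 0.066 and 0.077). The shift of this list ended with slide as a block (adjusted p = 0.791) and without any 1 of 3 arrays, WT4, KO1 or KO5 (highest adjusted p = 0.077).

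Among lists of liver cell types, those of endothelial cells, macrophages and stellate cells were shifted upward and that of hepatocytes downward, none of them with an estimated correlation, and those of cholangiocytes, B cells, T and NK cells, neutrophils and erythroid cells were not shifted. Endothelial markers rose for 3 of 24 (10 adjusted over the list alone; median 0.35, 0.74 within slide 2, adjusted p = 1.0e-06, and adjusted p = 0.612 with an estimated correlation), and all 5 knockout arrays lay above all wild-type arrays. The 3 were the lymphatic receptor gene Flt4 (0.58 ± 0.12), the nuclease gene Dnase1l3 (0.58 ± 0.12) and Fcgr2b (0.74 ± 0.18), at 0.80, 1.01 and 1.43 within slide 2, and each lost its call without some array (highest adjusted p = 0.070, 0.060 and 0.087). Macrophage and Kupffer cell markers rose for 2 of 29 (4 adjusted over the list alone; median 0.26, 0.56 within slide 2, adjusted p = 0.018, and adjusted p = 0.790 with an estimated correlation), namely the scavenger receptor gene Cd163 (0.91 ± 0.22, 0.80 within slide 2) and the Fc receptor gene Fcgr3 (0.81 ± 0.20, 1.52 within slide 2). Cd163 lost its call without any 1 of 7 arrays and Fcgr3 without any 1 of 9 (highest adjusted p = 0.110 and 0.086), and the list lost its shift without WT3, WT5, KO2 or KO3 (highest adjusted p = 0.179, without KO2). Adgre1, the F4/80 antigen gene, did not differ detectably (0.00 ± 0.35). On WT5, the only wild-type array of slide 2, both lists were low, with a median of -0.39 against the other wild-type arrays in each. Fcgr2b and Fcgr3 were also low on WT5. The larger values of these lists and genes within slide 2 therefore partly reflect that array. Stellate cell and fibrosis markers had 1 riser among 30 (0 adjusted over the list alone), Bgn (0.34 ± 0.08, 0.21 within slide 2), whose call was lost without any 1 of 9 arrays with a highest adjusted p = 0.103 (list median 0.21, 0.20 within slide 2, adjusted p = 0.0017, and adjusted p = 0.691 with an estimated correlation). Hepatocyte markers changed for 0 of 28, with a median of -0.10, -0.23 within slide 2 (adjusted p = 0.018, and adjusted p = 0.747 with an estimated correlation). That shift was lost without WT4, KO1 or KO2 (highest adjusted p = 0.157) and with quantile normalisation, and it did not pass without scaling (adjusted p = 0.061). The lowest p among them belonged to Asgr1 (-0.18 ± 0.06, adjusted p = 0.103).

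Inflammatory genes gave a mixed result. Of 27 cytokine and inflammatory signalling genes 1 rose (0 adjusted over the list alone), Il6, above background on 1 wild-type and 4 knockout arrays. It was at least 1.44-fold higher (at least 1.20-fold within slide 2), and its call was lost without any 1 of 6 arrays (highest adjusted p = 0.108). The list median was 0.34, 0.58 within slide 2 (adjusted p = 0.046, and adjusted p = 0.762 with an estimated correlation), and its shift was lost under 18 of 27 alternatives, among them without KO2 (adjusted p = 0.547). The chemokine gene Ccl2 differed by -0.12 ± 0.56 (adjusted p = 0.921), and Tnf was not above background on enough arrays to be tested. Genes of MHC class II presentation had positive differences for 11 of 11 members, with 0 called. The list median was 0.52, 0.50 within slide 2 (adjusted p = 0.0082, and adjusted p = 0.740 with an estimated correlation). Its lowest p belonged to Cd86 (0.61 ± 0.20). Acute phase genes had 0 of 25 called (2 adjusted over the list alone; median 0.27, 0.32 within slide 2, adjusted p = 0.0082, and adjusted p = 0.747 with an estimated correlation), with Crp at 0.50 ± 0.13 (adjusted p = 0.055). Without KO2 the shifts of these lists ended (adjusted p = 0.0997 for MHC class II and 0.115 for the acute phase), and with slide as a block that of MHC class II did (adjusted p = 0.065).

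Genes with higher expression in female liver fell, 5 of 22 measured (9 lower and 2 higher adjusted over the list alone; median -0.76, -0.61 within slide 2, adjusted p = 0.0013, and adjusted p = 0.371 with an estimated correlation), and the shift did not pass with slide as a block (adjusted p = 0.067). Besides Hamp2 these included the cytochrome P450 gene Cyp2a4 (-0.76 ± 0.11, -0.84 within slide 2) and the hydroxyacid oxidase gene Hao2. Hao2 was above background on 1 knockout array and at least 3.96-fold lower (at least 2.74-fold within slide 2), and it lost its call without any 1 of 6 arrays (highest adjusted p = 0.060). The labels do not give the sex of the mice. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were above background on all 10 arrays. At least 1 of 4 probes of Xist, the RNA of the inactive X chromosome, was so on 2 arrays, WT1 and KO1. Over the 10 arrays the brightest probe ran from 2.42 to 2.88 for Eif2s3y, from 0.90 to 1.68 for Ddx3y and from -7.27 to -4.57 for Xist. These levels argue against a female sample on any array. The 5 genes were chosen after the list values were seen. The male-biased list was not shifted (median 0.12, -0.25 within slide 2, adjusted p = 0.262). It was shifted upward without KO2 (median 0.29, adjusted p = 0.0021) and with array weights (adjusted p = 0.032). Its 1 riser of 26 was the receptor gene Egfr (2.14-fold, with a standard error of 0.25 on the log2 scale, and 0.82 within slide 2), whose call was lost without any 1 of 5 arrays (highest adjusted p = 0.084). Of 34 drug metabolism genes 4 fell (11 lower and 3 higher adjusted over the list alone; median -0.32, -0.34 within slide 2, adjusted p = 0.00044, and adjusted p = 0.504 with an estimated correlation). Among them were Cyp2a5 (-0.64 ± 0.09) and the glutathione transferase genes Gstt3 (-1.23 ± 0.19) and Gstt1 (-0.77 ± 0.16), at -0.71, -0.83 and -0.98 within slide 2. Gstt1 lost its call without any 1 of 6 arrays (highest adjusted p = 0.071).

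Of 27 genes of gluconeogenesis, glycogen and insulin signalling 1 fell (1 higher and 2 lower adjusted over the list alone; median -0.19, -0.31 within slide 2, adjusted p = 0.030, and adjusted p = 0.740 with an estimated correlation), the glucokinase regulator gene Gckr (-0.41 ± 0.10, -0.40 within slide 2). Its call was lost without any 1 of 8 arrays (highest adjusted p = 0.106) and the list shift without KO2 (adjusted p = 0.108) and with quantile normalisation (adjusted p = 0.128). Pck1, the gluconeogenic carboxykinase gene, differed by 0.46 ± 0.13 (adjusted p = 0.059). Clock and output genes had 0 of 19 called (median -0.44, -0.52 within slide 2, adjusted p = 0.030, and adjusted p = 0.691 with an estimated correlation; lowest p for Clock, 0.28 ± 0.09). NRF2 targets had 0 of 22 called (median -0.11, -0.17 within slide 2, adjusted p = 0.018, and adjusted p = 0.612 with an estimated correlation; lowest p for Nfe2l2, -0.45 ± 0.12). With slide as a block the glucose list had an adjusted p = 0.067, the clock list 0.109 and the NRF2 list 0.109. The clock list also lost its shift without WT3, WT4, KO2 or KO3 (highest adjusted p = 0.077) and the NRF2 list without KO1 (adjusted p = 0.075). The NRF2 shift was further lost with quantile normalisation, alone or after normexp correction (adjusted p = 0.089 and 0.091). That of the clock list was lost with the stricter filter on dim probes and with the mean of a gene's probes.

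The other 14 tested lists were not shifted, with adjusted p-values from 0.072 for bile acid genes to 0.937 for cholangiocyte markers. Among 20 genes of lipoproteins and cholesterol efflux Apom, an apolipoprotein of high-density lipoprotein, rose 1.99-fold (0.99 ± 0.08, 1.03 within slide 2) and Apoc2, the lipoprotein lipase cofactor, fell 1.36-fold (-0.45 ± 0.08, -0.57 within slide 2), with a list median of -0.06, also -0.06 within slide 2, while Apoe differed by -0.11 ± 0.08 (adjusted p = 0.437). Bile acid genes had 0 of 24 called (median -0.16, -0.31 within slide 2, lowest p for Abcc3, -0.57 ± 0.17), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.02 ± 0.49. The bile acid list was shifted downward under 5 of 27 alternatives, without KO3 or KO4, without scaling, with no filter on dim probes and with the replicate number as a block (adjusted p from 0.0028 to 0.030). The list of endoplasmic reticulum stress (median 0.09, -0.08 within slide 2) held Asns as its 1 riser of 21, and it was shifted upward without WT3 or KO3 (adjusted p = 0.045 and 0.033). The fetal and tumour list (median 0.14, 0.41 within slide 2) held the growth factor gene Igf2 (0.79 ± 0.14, 0.95 within slide 2) as its riser among 12 (1 higher and 1 lower adjusted over the list alone). The cell cycle list (median -0.06, -0.05 within slide 2) held the replication licensing gene Mcm2 (-0.87 ± 0.22, -0.72 within slide 2) as its 1 faller of 23 (0 adjusted over the list alone), whose call was lost without any 1 of 9 arrays (highest adjusted p = 0.121). Without KO5 that list was shifted downward (median -0.38, adjusted p = 0.0030). Cholangiocyte markers, with a median of 0.15 (0.24 within slide 2) and a mean of -0.11, held Lamb3 (-1.29 ± 0.23, -1.75 within slide 2) as 1 faller of 13 (2 adjusted over the list alone). Pancreas markers, with a median of -0.03 (-0.48 within slide 2) and a mean of 0.14, held Rnase1 as 1 riser of 7. WT5 was high for this list, with a median of 0.93 against the other wild-type arrays, which the value within slide 2 partly reflects. Rnase1 was above background on 2 wild-type arrays and at least 2.16-fold higher (at least 1.47-fold within slide 2), and its call was lost without any 1 of 6 arrays (highest adjusted p = 0.081).

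No member was called in the lists of interferon response (29 genes, median 0.05, 0.30 within slide 2, Psmb8 at 0.39 ± 0.21), B cells (14 genes, median 0.00, -0.17 within slide 2, Cd37 at 0.91 ± 0.39), T and NK cells (23 genes, median 0.08, -0.29 within slide 2, Tcf7 at 0.25 ± 0.08), neutrophils (6 genes, median 0.43, 0.33 within slide 2, Csf3r at 0.36 ± 0.19), erythroid cells (7 genes, median -0.10, -0.07 within slide 2, Klf1 at -0.53 ± 0.19), skeletal muscle (5 genes, median 0.10, -0.01 within slide 2, Myh2 at 1.19 ± 0.58) or immediate early and heat shock genes (24 genes, median 0.24, 0.07 within slide 2, Klf4 at 0.49 ± 0.18), the gene named being that with the smallest p. The interferon list was shifted downward without KO2 (median -0.29, adjusted p = 0.0083), and those of T and NK cells without KO1 (adjusted p = 0.0498) and of immediate early genes without KO3 (adjusted p = 0.024) were shifted upward. WT5 was high for the lists of B cells and of T and NK cells (medians of 0.46 and 0.42 against the other wild-type arrays). Their negative medians within slide 2 therefore partly reflect that array. Only Cfd and Fabp4 of 11 fat-tissue markers were measured on enough arrays, too few for a list test, and Fabp4 differed by -0.25 ± 0.14 (adjusted p = 0.300). In all, 19 of 34 lists were shifted, 8 up and 11 down, 0 with an estimated correlation and 6 by fry, a rotation test of each list alone. The 6 were the lists of lipid droplets, fatty acid oxidation, fatty acid uptake, ribosomal proteins, female-biased genes and drug metabolism. Because 14 of 100 splits of the arrays, the real one among them, gave at least 19 shifted lists, the number of shifted lists does not exceed what regrouping gave.

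**Figure D3:**
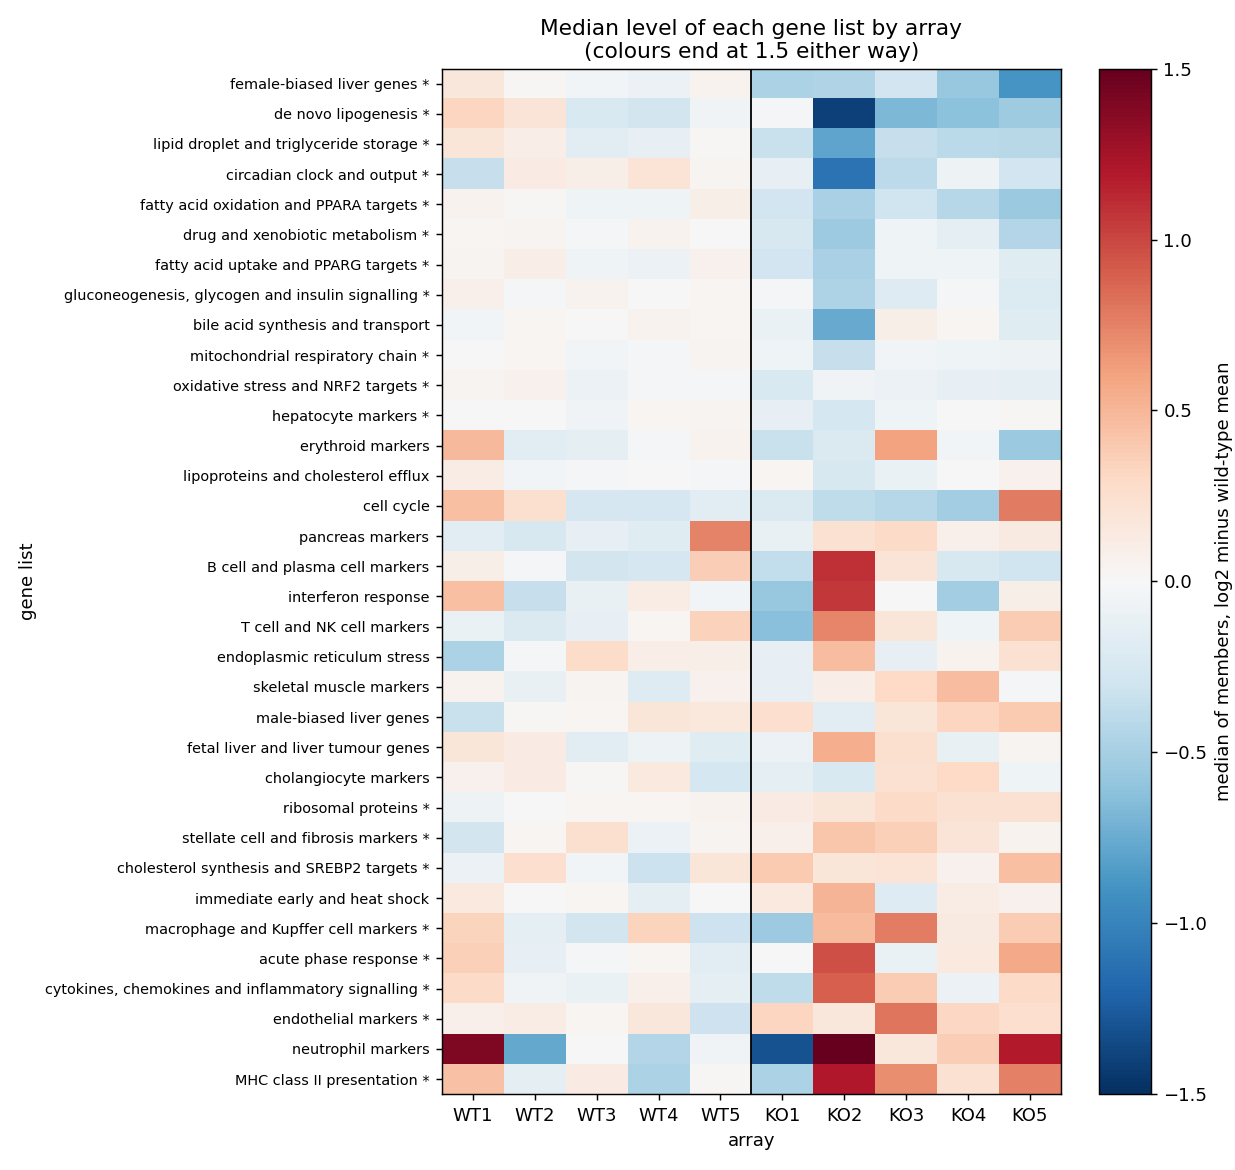
Median log2 difference of each list's members from their wild-type mean on each of the 10 arrays, with lists in rows ordered by their overall difference, red above and blue below the wild-type mean, and an asterisk on the 19 shifted lists. The lipid droplet row (overall median -0.53) is blue on all 5 knockout arrays, and KO2 stands out in several immune rows.

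On chromosome 6 within 20 Mb of Nr2c2, 20 of 194 tested genes changed (10.3%), against 5.91% of genes placed elsewhere (two-sided Fisher's exact test, p = 0.020). Without Nr2c2 and the cDNA probe within it the count was 19 of 192 (9.90%, two-sided Fisher's exact test, p = 0.030). The extracellular matrix gene Fbln2, 0.89 Mb away, rose 2.72-fold (1.44 ± 0.14), Vmn1r53 was above background in the knockout alone, and the mitochondrial gene Chchd6, 2.79 Mb away, fell 1.93-fold (-0.95 ± 0.08). The N-acetyltransferase genes Nat8f5 and Nat8f3 fell together. Nat8f5 differed by -3.44 ± 0.64, and Nat8f3, above background on 1 knockout array, was at least 2.30-fold lower. Further decreases were those of Sfxn5 (-0.91 ± 0.15), Eva1a (-0.82 ± 0.19), Anxa4 (-0.81 ± 0.09), Uroc1 (-0.69 ± 0.15), Pcyox1 (-0.63 ± 0.15), Mgll (-0.53 ± 0.13), Suclg2 (-0.38 ± 0.07) and Mcm2. Further increases were those of Dysf (0.80 ± 0.15), Eif4e3 (0.79 ± 0.13), Adamts9 (0.77 ± 0.19) and Eogt (0.46 ± 0.07). The remaining 3 of the 20 were the cDNA probe within the Nr2c2 locus, an unnamed transcript at 108623976 to 108624035 (-0.83 ± 0.13) and another at 86003819 to 86003878 (0.61 ± 0.14). The calls of Nat8f3, Nat8f5, Dysf and Suclg2 were lost without WT2 (adjusted p = 0.053, 0.053, 0.057 and 0.060), and those of Eva1a, Uroc1, Pcyox1, Mgll, Adamts9, Mcm2 and the transcript at 86003819 without any 1 of at least 6 arrays (highest adjusted p from 0.081 to 0.121).

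**Figure D4:**
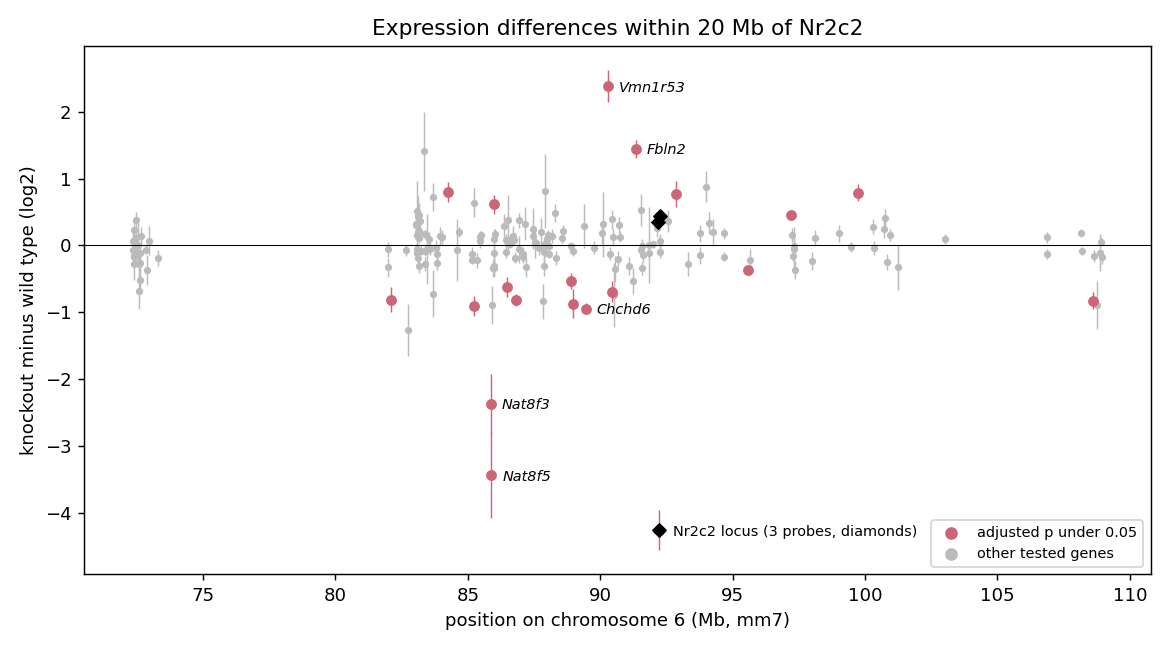
Log2 difference, knockout minus wild type, with bars of 1 standard error, for 194 tested genes against position on chromosome 6 in Mb (mm7), within 20 Mb of Nr2c2. Red points are the 20 genes with an adjusted p under 0.05, and black diamonds are the 3 probes of the Nr2c2 locus at 0.36, 0.44 and -4.26. The points of the cDNA probe (-4.26) and of Vmn1r53 are fitted values against a group with no array above background, where only the bounds, at least 5.41-fold and 1.86-fold, hold.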

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

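The tests of slide, of position on chromosome 6, of fat tissue and of hepatocyte share in this part were chosen after the results were seen. A sample was taken as set apart when its gap to the nearest other sample of its group was over 0.71 of the group's range. Of 204 groups examined, 17 had such a sample, where chance sets apart about 1 in 20, and 9 of the 17 samples were KO2.

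KO2 was set apart at Scd1 (ratio 0.948, signal 2.83 against 7.26 on the nearest knockout array), Gckr (0.796), Tcf7 (0.786), Acsm2 (0.785), Plin4 (0.782), Uroc1 (0.778), Rpl10a (0.767), Gstt1 (0.720) and Rassf4 (0.710). For Acsm2, Plin4 and Tcf7 it was the highest knockout array, and for the other 6 genes the lowest. KO3 was the lowest knockout array for the unnamed transcript near 108623976 on chromosome 6 (0.714). Among wild-type arrays, WT1 was set apart for the cDNA probe in the Nr2c2 locus (0.712), Adamts9 (0.760) and Asgr1 (0.772), WT3 for Eif4e3 (0.905), WT4 for Socs2 (0.728), and WT5 for Fcgr2b (0.773) and Fcgr3 (0.761).

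The 938 changed genes exceeded every other grouping of the arrays that was drawn: of 100 splits into 5 and 5, 1 gave as many, the real one, and the highest of the others gave 16. That argues against a random division of the arrays as the source of that count, as far as 100 splits can show. Every other split mixed the genotypes, which widens the spread within its parts and lowers its count. For the 19 shifted lists chance stays open, since 14 of 100 splits, the real one among them, gave as many and the highest of the others gave 22. The other splits shifted a median of 13 lists with 3 wild-type arrays in the larger part, and of 15 with 4. At the preset correlation, camera thus called many lists under regrouping too.

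WT1 to WT4 shared a slide that held no knockout array, so a difference between slides was weighed as an explanation of the changed genes. WT5 was hybridised with KO1 to KO3 on slide 2. For the 461 genes called without WT5, its median position was 0.015 on a scale from 0 at the other wild-type arrays to 1 at the knockout arrays (quartiles -0.17 and 0.28), and 385 lay nearer to wild type. That argues against slide as the cause for most of these 461 genes, though it rests on 1 array. Of the 938 changed genes 402 passed without WT5, and the others are not covered. Slides 3 and 4 hold 1 knockout array each and their effect stays open.

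The decrease of fat-storage genes, with a median of -1.94 over the 11 that fell and -0.53 over all 31, was set against 2 technical explanations. Fat tissue attached to the wild-type pieces would bring its abundant transcripts, but 2 of 11 fixed fat-tissue markers, Cfd and Fabp4, were above background on at least 4 wild-type arrays, and 8 of 11, among them Adipoq, Lep and Plin1, were on 0. Among these 11 markers, the values that go with that explanation are the 52.8-fold fall of Cfd and Retn above background on 3 wild-type and 0 knockout arrays. Fabp4, which liver cells other than hepatocytes also express, differed by -0.25. Adipoq, Lep and Plin1 have 1 probe each, so some fat tissue on the wild-type pieces stays open. A smaller share of hepatocytes would lower their markers alike, yet the hepatocyte median was -0.10 (quartiles -0.21 and -0.05). Of 28 markers 27 lay above -0.53, the lowest at -0.56. All 28 lay above -1.94, but that is the median of genes chosen for having fallen. Scaling to each array's 75th percentile can take up part of a shift shared by many transcripts, so a smaller loss of hepatocytes stays open. The hepatocyte list was itself shifted downward and the endothelial, macrophage and stellate cell lists upward. Loss of the receptor, and a difference in liver fat content that was not measured here, may both account for the decrease and stay open. Of the fat-storage genes that fell, Mgll lies within 20 Mb of Nr2c2 and Cidec 21.3 Mb from it. For these genes the causes tied to position, taken up in the next paragraph, stay open as well.

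Changed genes lay more densely around Nr2c2 than elsewhere, also with the 2 entries of the deleted locus itself left out (9.90% within 20 Mb against 5.91%, Fisher's exact p = 0.030, adjusted p = 0.049 over 10 comparisons of position). However, 2 of 59 other 40 Mb windows had as high a share. Fisher's test takes genes as independent, while neighbours such as Nat8f3 and Nat8f5 fell together. The 10 comparisons also overlap, with the window taken both with and without the locus. The p-value may thus be too small, and it does not decide against an even spread. At an adjusted p under 0.01 the shares were 3.65% and 1.03% (Fisher's exact p = 0.0044), and the highest of the 59 windows reached 3.42%. Donor-strain DNA kept around a targeted gene may raise such a share, and the comparison with the rest of chromosome 6 (9.90% against 7.96%, Fisher's exact p = 0.455, and 3.65% against 1.33%, p = 0.061, at an adjusted p under 0.01) does not decide on it, since that rest itself exceeded the other chromosomes (7.96% against 5.82%, Fisher's exact p = 0.034, adjusted p = 0.049). The labels give C57BL/6 for both groups and no breeding history, so donor DNA, an effect of the targeted allele on its neighbours and loss of the receptor cannot be told apart. Cidec, Pparg, Rassf4 and Adipor2, 21.3, 23.3, 24.4 and 27.1 Mb from Nr2c2, lie outside the window on the same chromosome. Mgll, a fat-storage gene that fell, lies inside it.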

How the results depend on the processing

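The count of 938 changed genes stayed within 1.5 times under 8 alternatives of processing (870 to 1336) and left that range under others: 471 with the deposited values unscaled, 247 with no filter on dim probes (27667 genes tested), 35 with slide as a fixed block, 2 within slide 2, 1431 with slide as a random block (its correlation of -0.09 says nothing of slides), 321 with the Welch test, 219 with a 2-fold minimum and 169 at an adjusted p under 0.01. Without KO2 and KO4 together, chosen after seeing the data, it was 530, of which 421 were among the 938. Leaving out each array gave 297 to 1194. Fixed block and slide 2 leave 1 wild-type array in the contrast, the thresholds are stricter, and for the other settings the cause was not tested. With the replicate number as a block it was 164, 157 of them among the 938. Same-numbered arrays deviated with correlations of -0.03, -0.21, -0.12, 0.04 and -0.05, and 0 of 5 wild-type arrays correlated best with their own number, so the samples share only a number.

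Nr2c2 stayed positive, from 0.28 to 0.46, and passed only with the mean of its 2 probes (0.40, adjusted p = 0.023). Shifted lists numbered 14 to 20 except with an estimated correlation (0) and with fry (6), which test against a wider spread or the list alone. The interferon list turned negative and passed without KO2 (-0.29, against -0.06 to 0.20 without other single arrays). KO2 lay at 1.06 from the wild-type mean on that list, and the other knockout arrays between -0.57 and 0.09. The pancreas list (-0.03) was at -0.48 with slide as a fixed block and within slide 2, and it passed upward without WT5 (0.44, adjusted p = 0.043). On WT5 the pancreas list lay at 0.75, against -0.23 to -0.12 on the other wild-type arrays. These pancreas values therefore turn on WT5, the only wild-type array of slide 2. Why KO2 and WT5 differed was not tested. Of 2530 values of named genes 1951 kept their side of the threshold, 556 lost a call, 23 gained one and 0 reversed. Of 917 values of lists 804 kept it, 96 lost a shift and 14 gained one. Of 78 named genes that changed, 42 kept the call without each array in turn. Dim probes limit the rest: 17908 of 41174 were not above background often enough to be tested.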

Other observations

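The tests of gene groups and of the X chromosome in this part were chosen after the values were seen, so their p-values are no independent support. Annexins, membrane-binding proteins, fell for 5 of 11 measured members and rose for 0. Anxa2 fell by 1.36 on the log2 scale (adjusted p = 0.00055), Anxa8 by 1.25, Anxa4 by 0.81, Anxa5 by 0.64 and Anxa7 by 0.37. Their median was -0.30, and -0.29 within slide 2 (camera p = 0.00020, and p = 0.030 with an estimated correlation, both unadjusted). Peroxins, the Pex genes, were tested in the same way, and 4 of 17 fell and 0 rose. The peroxin median was -0.28, also within slide 2 (camera p = 2.0e-07, and p = 0.024 with an estimated correlation, both unadjusted).

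Meg3 and Mirg lie in the imprinted Dlk1-Dio3 region on chromosome 12. All 3 Meg3 probes were higher in the knockout (3.79, 3.73 and 2.41, the last with an adjusted p = 0.062 over probes), as was the Mirg probe (at least 2.67-fold). Of 26 measured genes of serine and asparagine synthesis and of the response to amino acid shortage, 18 had positive differences, and the group was not shifted (median 0.11, camera p = 0.149 with no adjustment, and p = 0.585 with an estimated correlation). Asns was the 1 that rose and 2 fell, Gdf15 (-1.49) and Gpt2 (-0.78). Psat1 (1.69), Mthfd2 (1.41), Phgdh (1.21), Chac1 (1.19), Slc7a5 (0.80), Pck2 (0.62) and Atf4 (0.26) had positive differences that did not pass the test (adjusted p from 0.059 for Slc7a5 to 0.456 for Phgdh), and Vldlr a negative one (-1.49, adjusted p = 0.093). Asns lies on chromosome 6, 84.6 Mb from Nr2c2. Of 8 growth hormone response genes Socs2 and Egfr rose, while Igf1 differed by 0.05 and Cish by 1.70 (adjusted p = 0.865 and 0.358). The median of the group was 0.54, and 0.42 within slide 2 (camera p = 0.046, and p = 0.124 with an estimated correlation, both unadjusted). The calls of Socs2 and Egfr depended on single arrays, as given above.

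Changed genes were also frequent on the X chromosome, 45 of 488 (9.22%) against 5.86% on the autosomes (two-sided Fisher's exact p = 0.0034, adjusted p = 0.015 over 10 such comparisons of position). The labels do not give the sex of the mice. Y-linked genes were above background on all 10 arrays and Xist signal was low, which argues against female samples.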
